A study of Mus musculus with 18 samples.

How the data were processed

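RNA was measured by sequencing in epithelial cells that had been sorted from the ileum of female mice, in 18 libraries: 6 from virgin, 6 from pregnant and 6 from pseudopregnant mice. Per the labels' protocols, RNA was extracted with the RNeasy Plus Micro kit, and libraries were made with the NEBNext Ultra II Directional kit after poly(A) enrichment. The animals were kept on RM3 chow for breeding and RM1 for maintenance and the experiment. The labels do not give the day of pregnancy, how pseudopregnancy was induced, the hour of collection, the markers used for sorting or any batch.

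The deposited values are read counts per Ensembl gene, 1 table per library, with no normalization. The submitters' processing notes name FastQC 0.11.5, HISAT2 2.0.4, featureCounts, Subread 2.0.0, DESeq2 1.24.0 and the mouse build GRCm38. The strand setting of the counting and the annotation release are not given in the sources used here, so overlapping and antisense genes may share reads in these counts, as may genes with near-identical copies. Each table held 47729 genes. The GENCODE M21 annotation of GRCm38 gave symbols and positions for 47310 of them, and the 419 others held at most 0.029% of a library's counts. Total counts ran from 24.9 to 37.3 M per library (median 31.5). Counts of any 2 replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 35.5 to 455.8), so no library was counted as a duplicate of another.

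Groups and replicate numbers came from the titles. The design, the named-gene rule, the 39 gene lists and most alternatives were chosen before the data were examined. Genes were filtered by edgeR's filterByExpr with the 3 groups, which left 14675 genes. Trpv6, named by the rule, fell below that filter. Libraries were scaled by TMM, and edgeR 4.0.16 (R 4.3.3) fitted a quasi-likelihood model with 1 mean per group to all 18 libraries, with the newer dispersion method (legacy = FALSE, not the default of that version). Each of the 3 pairwise contrasts was tested two-sided, with Benjamini-Hochberg adjustment over the 14675 genes and a threshold of 0.05. Fold changes are log2 values with their standard error (SE). Group values are means ± SD of TMM-scaled CPM, n = 6. The ranges of Epcam and Ptprc over the 18 libraries are not TMM-scaled.

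Gene lists were tested with camera (limma 3.58.1), which compares a list with all other genes, with the inter-gene correlation preset at 0.01. Adjustment was over the 35 lists with at least 5 tested members. The lists of T cells, B cells and stroma had fewer tested members and the red blood cell list had none, so these were not tested as lists and only their scores and summed CPM are given. Camera with a correlation estimated per list and fry, a rotation test of whether a list's genes move on balance in 1 direction, were the alternatives. Members were also counted after adjustment over the list alone. That adjustment was within 1 list and not over the 35 lists.

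Genes are named by this rule. Of the genes past the threshold, the 12 with the highest and the 12 with the lowest fold change are named, with a mean CPM over the 12 libraries compared of at least 2, no predicted gene and at least 5 of 6 libraries on 1 side of the other group's median. Where fewer than 5 genes passed, the 10 genes of smallest p are named with values only. Of each list past the list test or with at least 3 members past the gene test, the 4 members of smallest p were computed. A set of genes fixed by name (Slc5a4a, Slc5a4b, Slc5a1, Slc2a2, Slc2a5, Lgr5, Olfm4, Mki67, Apoa4, Fgf15, Fabp6, Trpv6, S100g, Esr1, Pgr, Prlr, Epcam and Ptprc) was computed whatever the test gave.

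A score of a list in a library is the mean over its tested members of the log2 CPM (prior count 2) minus the gene's mean over the 18 libraries. The villus-minus-crypt score is the absorptive enterocyte score minus the proliferation score. As a covariate it therefore contains these 2 lists, and their own values with it are not read as a test. It also shares 4 genes with the sugar transport list and 1 with that of fat uptake. The length slope of a library is the slope of the same deviations on log2 transcript length over 4723 well expressed genes. Transcript length here means the number of bases covered by all annotated exons of a gene. Correlations across libraries were tested with 100000 permutations, and differences between groups of 6 with exact permutation tests.

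The alternatives chosen beforehand for genes were scaling by DESeq2's size factors or the upper quartile, no low-count filter or CPM of at least 1 in 6 libraries, DESeq2 1.42.0, limma-voom, a robust fit and only the 12 libraries compared. They were also a threshold of 0.01 or an added log2 fold change of at least 1, mitochondrial genes left out, the replicate number as a block, 1 surrogate variable (sva 3.50.0), and each library left out in turn. Lists were also tested with DESeq2's size factors, the CPM filter, the block and each library left out. The default dispersion method of edgeR, 2 surrogate variables, the length slope and the villus-minus-crypt score as covariates were added after the data had been seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

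The steps were tested on simulated counts for all 14675 genes with 200 genes changed. For pregnant against virgin libraries, 14.9% of the genes changed by 1.5-fold, 56.7% of those changed by 2-fold and 97% of those changed by 4-fold were called, with 8 of 14455 unchanged genes. For pseudopregnant against virgin libraries these were 11.9%, 62.7% and 93.9%, with 6 unchanged genes, and for pregnant against pseudopregnant libraries 22.4%, 59.7% and 98.5%, with 4. A list of 20 simulated genes changed by 1.5-fold passed with an estimated correlation in each comparison (adjusted p = 0.000168, 6.11e-07 and 4.2e-05). In these simulations, where genes vary independently, 1, 0 and 0 of the fixed lists passed with the preset correlation. The genes of the real lists do not vary independently: the median of the estimated correlations was 0.28 to 0.29 and the highest 0.92.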

Results

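Epithelial cells sorted from the ileum, the last part of the small intestine, of female mice were profiled by RNA sequencing in 18 libraries. They formed 3 groups of 6 by mating status: virgin, pregnant and pseudopregnant. Pseudopregnancy is a luteal state of mice without embryos, so the 3 groups set what pregnancy and pseudopregnancy share beside what differs between them. The labels give no day of pregnancy and no hour of collection, so stage or hour may differ between the groups too. The series title names the growth of the maternal gut in reproduction as the subject. Libraries held 30.9 ± 1.79 M (mega) counts in the virgin, 31.3 ± 4.75 M in the pregnant and 30.9 ± 1.53 M in the pseudopregnant group (mean ± SD, n = 6). The labels do not state that the replicates of a group are separate animals, so all p-values measure the spread between these samples.

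The epithelial marker Epcam stood at 1748 to 3150 CPM in all 18 libraries and the pan-leukocyte gene Ptprc at 0.21 to 0.664 CPM. Transcripts of the mitochondrial genome took 6.27% ± 1.24 of counts in virgin, 6.11% ± 1.73 in pregnant and 7.13% ± 1.26 in pseudopregnant libraries. Genes of ribosomal proteins took 4.05% ± 1.11, 3.33% ± 1.14 and 3.09% ± 0.776. The first principal component held 39.8% of the variance, and its group medians were -8.9, 4.5 and 23.0 in virgin, pregnant and pseudopregnant libraries. Over 4723 well expressed genes, the correlation of a gene with this component rose with transcript length (Spearman's rho 0.62 across genes, which are not independent replicates). The villus-minus-crypt score, which sets markers of absorptive enterocytes against those of dividing crypt cells, was highest in pregnant replicate 3 (1.42), virgin replicate 3 (1.19), pseudopregnant replicate 3 (0.95) and pregnant replicate 4 (0.83), and lowest in virgin replicate 2 (-0.83).

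The first comparison asked which transcripts differ between pregnant and virgin ileal epithelium. Slc5a4a, which encodes a member of the sodium/glucose cotransporter family (chromosome 10, 76147451 to 76189265, plus strand, GRCm38), stood at 148 ± 67.8 CPM in pregnant and 65.1 ± 33.4 CPM in virgin libraries (log2 fold change 1.18, SE 0.36, n = 6 each). All 6 pregnant libraries lay above the virgin median. Bco1, the enzyme that splits beta-carotene to retinal (chromosome 8, 117095854 to 117133720, plus strand), stood at 47.1 ± 22.4 against 15.2 ± 4.01 CPM (log2 fold change 1.63, SE 0.35). The unannotated transcript Gm42427 (chromosome 5, 44137980 to 44143271, plus strand) stood at 44.1 ± 11.1 against 16.2 ± 3.76 CPM (1.44, SE 0.27). Dbp, Tef, Per3 and Nr1d2, of the circadian clock list, were higher in the pregnant libraries by 1.51 (SE 0.44), 0.90 (SE 0.23), 1.13 (SE 0.32) and 0.71 (SE 0.19) on the log2 scale. Each had all 6 pregnant libraries above the virgin median. None of these differences passed adjustment over all genes in the edgeR model with 1 mean per group (adjusted p = 0.49 for Gm42427 and 0.89 for the others).

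**Figure D1:**
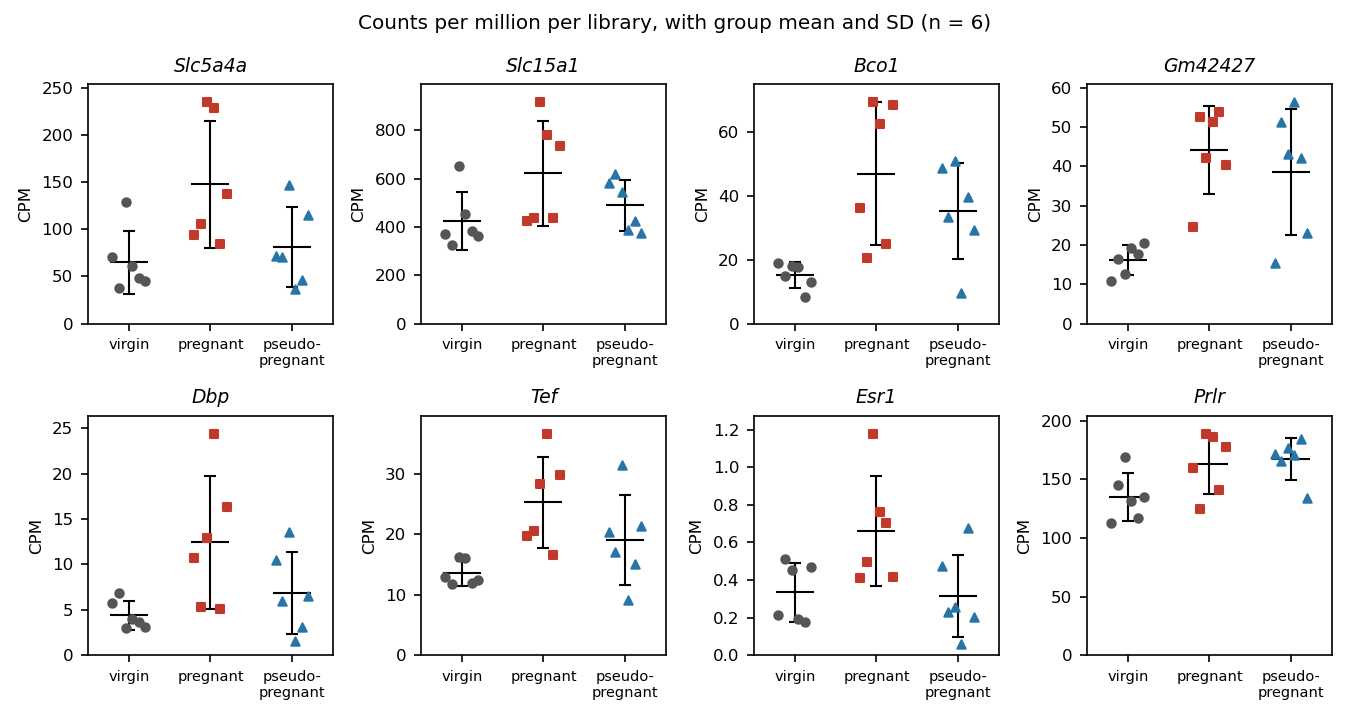
CPM (linear axes from 0) of 8 genes in each of the 18 libraries, with the mean (dash) and SD (bar) of each group of 6. Slc5a4a ran from 84.4 to 235 CPM in pregnant and from 37.6 to 129 CPM in virgin libraries, while Bco1 and Gm42427 had no pregnant library within the virgin range.

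In that model 0 of 14675 genes passed an adjusted p of 0.05. An unadjusted p under 0.05 was held by 540 (3.68%, 296 higher and 244 lower in pregnant libraries). Of 100 splits of the 12 pregnant and virgin libraries, the real one among them, 31 gave at least as many. The median of the other splits was 290, as told below. Limma-voom called 0 genes (528 at an unadjusted p under 0.05) and DESeq2 called 2 (786), namely Gm42427 (adjusted p = 0.0032) and Bco1 (adjusted p = 0.042). Over all alternatives the adjusted p of Gm42427 ranged from 0.00321 to 1 and that of Bco1 from 0.0423 to 1. The 2 groups did not overlap in 10 genes (0.07%, where chance gives 0.216%). The median SE of a fold change was 0.202. Others of the 10 genes of smallest p were Mbl2, a lectin of innate defence (log2 fold change 1.51, SE 0.34), the copper importer Slc31a1 (1.01, SE 0.23), Cyp3a44, a cytochrome P450 (1.98, SE 0.46), Zfp385b (0.93, SE 0.23) and Asap3 (1.12, SE 0.29). The others were Gm21887 (-0.99, SE 0.26) and Gm47283 (-1.04, SE 0.27), near-identical copies on the X and Y chromosomes whose reads cannot be told apart with certainty. The count of 540 fell to 223 without pregnant replicate 4, 265 without pregnant replicate 3, 315 without virgin replicate 2 and 331 without virgin replicate 1. It was 1953 without virgin replicate 3, 1382 without pregnant replicate 1 and 813 without pregnant replicate 5. With the villus-minus-crypt score as a covariate it was 250, and with no low-count filter, where more genes are tested, 989.

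Genes of absorptive enterocytes were higher in pregnant libraries as a list: 19 of 21 had positive fold changes, with a median of 0.44 (camera adjusted p = 1.6e-08, and adjusted p = 0.421 with an estimated correlation). Among them were the brush border peptidases Enpep (0.43, SE 0.19), Dpp4 (0.51, SE 0.23) and Mep1a (0.52, SE 0.24), and Ace (0.71, SE 0.33). Transporters of amino acids and peptides were positive in 19 of 20 (median 0.34, adjusted p = 2.27e-06, and adjusted p = 0.353 with an estimated correlation). Those of smallest p included the peptide transporter Slc15a1 (622 ± 216 against 424 ± 118 CPM, 0.55, SE 0.22), Slc3a1 (0.44, SE 0.17) and Slc7a15 (0.61, SE 0.26). The list of sugar transport was positive in 15 of 18 (median 0.36, adjusted p = 0.00011, and adjusted p = 0.505 with an estimated correlation). Besides Slc5a4a it held the fructose transporter Slc2a5 (0.50, SE 0.24), Slc5a9 (0.39, SE 0.22) and the main intestinal glucose importer Slc5a1 (0.28, SE 0.20). Adjusted over the list alone, 0 of 18 passed (adjusted p = 0.07 for Slc5a4a). Dietary fat uptake and chylomicron assembly were positive in 21 of 24 (median 0.18, adjusted p = 0.00011, and adjusted p = 0.564 with an estimated correlation). The cholesterol importer Npc1l1 was at 0.50 (SE 0.22) and Scarb1 at 0.92 (SE 0.37, and 0.54 without pregnant replicate 6). Slc5a4a has a neighbouring paralog, Slc5a4b, at 183 ± 74.2 against 140 ± 81.7 CPM (0.38, SE 0.37, and 0.17 to 0.69 when 1 library was left out), and how reads were shared between them is uncertain. The fold change of Slc5a4a was 0.75 with the villus-minus-crypt score as a covariate and 1.001 to 1.498 in the sets that left out 1 library.

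The circadian clock list was higher, with 13 of 17 genes positive (median 0.27, adjusted p = 4.67e-08, and adjusted p = 0.195 with an estimated correlation). Adjusted over the list alone, 6 of 17 passed: Tef and Nr1d2 (adjusted p = 0.0093 each), Per3 and Dbp (0.012 each), and Nr1d1 (0.65, SE 0.21) and Hlf (1.31, SE 0.46), these last named after their values were seen. Hlf did not pass without virgin replicate 4 or 5 or pregnant replicate 6 (0.57 without the last), nor Nr1d1 without pregnant replicate 3 or 6. Over all genes 0 passed. Hormone receptors were positive in 11 of 14 (median 0.25, adjusted p = 0.000618, and adjusted p = 0.421 with an estimated correlation). The estrogen receptor Esr1 stood at 0.661 ± 0.292 against 0.336 ± 0.157 CPM (0.999, SE 0.41) and the prolactin receptor Prlr at 163 ± 26.0 against 135 ± 20.4 CPM (0.27, SE 0.12). The mineralocorticoid receptor Nr3c2 was at 0.37 (SE 0.18) and the progesterone receptor Pgr at -0.03 (SE 0.52). Retinoid metabolism was positive in 7 of 11 (median 0.16, adjusted p = 0.022, and adjusted p = 0.505 with an estimated correlation), and adjusted over the list alone 1 of 11 passed, Bco1 (adjusted p = 0.002). All 8 genes of MHC class II, which present antigen, were positive (median 0.57, adjusted p = 0.00033, and adjusted p = 0.505 with an estimated correlation), with Cd74 at 1530 ± 618 against 1020 ± 744 CPM (0.58, SE 0.56, and 0.35 without virgin replicate 6 or 0.96 without virgin replicate 3). So were 23 of 31 genes of the interferon response (median 0.28, adjusted p = 0.000113, and adjusted p = 0.651 with an estimated correlation), with Gbp2 at 0.80 (SE 0.43) and Irf1 at 0.36 (SE 0.22), or 0.36 and 0.19 without pregnant replicate 3.

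Lists of other cell types and states were lower in pregnant libraries. All 22 enteroendocrine genes were negative (median -0.40, adjusted p = 2.27e-06, and adjusted p = 0.421 with an estimated correlation), with the proglucagon gene Gcg at -0.52 (SE 0.24, and -0.78 without pregnant replicate 5) and Chgb at -0.48 (SE 0.22, and -0.195 without virgin replicate 4). All 18 goblet cell genes were negative (median -0.29, adjusted p = 0.00011, and adjusted p = 0.505 with an estimated correlation), with Agr2 at -0.56 (SE 0.23) and Zg16 at -0.68 (SE 0.34, and -0.38 without virgin replicate 4). All 34 genes of proliferation (median -0.19, adjusted p = 0.00011, and adjusted p = 0.651 with an estimated correlation), among them Pcna (-0.25, SE 0.16) and Aurka (-0.31, SE 0.20), were negative. So were all 30 of ribosome biogenesis and MYC targets (median -0.23, adjusted p = 4.75e-06, and adjusted p = 0.564 with an estimated correlation), among them Gar1 (-0.58, SE 0.26) and Myc (-0.45, SE 0.26). Mki67 itself was at -0.02 (SE 0.31). The 18 genes of dissociation and immediate early response were also all negative (median -0.16, adjusted p = 0.00011, and adjusted p = 0.421 with an estimated correlation). Nr4a1 was at -0.66 (SE 0.23), and the heat shock paralogs Hspa1a and Hspa1b at -0.65 (SE 0.30) and -0.61 (SE 0.28, and -0.41 without virgin replicate 4), whose reads may be shared. In all, 14 of 35 lists passed with the preset correlation, 9 higher and 5 lower.

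With an estimated correlation 0 of these 14 lists passed. Fry also called 0 lists (smallest adjusted p = 0.253), and over all alternatives the adjusted p of these lists ran from 7.91e-11 (absorptive enterocyte) to 0.891 (dietary fat uptake and chylomicron assembly). Single libraries ended some calls: without virgin replicate 6 those of MHC class II (median 0.34), interferon response (0.14) and retinoid metabolism (0.16), and without pregnant replicate 3 those of proliferation (-0.11) and retinoid metabolism (0.20). Without virgin replicate 5 that of retinoid metabolism (0.074) ended, and without virgin replicate 4 that of goblet cell genes (-0.19). Medians moved by over 1.5 times without virgin replicate 3 (proliferation -0.32, goblet -0.43, fat uptake 0.35, MHC class II 0.94, interferon 0.45), virgin replicate 4 (enteroendocrine -0.19, retinoid 0.34) and virgin replicate 2 (sugar 0.23, interferon 0.17). They also did without virgin replicate 5 (proliferation -0.13), virgin replicate 6 (fat uptake 0.11), pregnant replicate 6 (sugar 0.22) and pregnant replicate 3 (sugar 0.23, fat uptake 0.090, interferon 0.13, dissociation -0.26, ribosome biogenesis -0.13). With the villus-minus-crypt score as a covariate, the calls of sugar transport (0.046), fat uptake (-0.029), MHC class II (0.18), interferon response (0.006), retinoid metabolism (0.051) and ribosome biogenesis (0.028) ended. With 2 surrogate variables 8 calls ended: proliferation (0.049), goblet cell (-0.15), sugar transport (0.011), fat uptake (-0.002), MHC class II (0.21), interferon response (-0.007), retinoid metabolism (0.076) and ribosome biogenesis (-0.002).

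**Figure D2:**
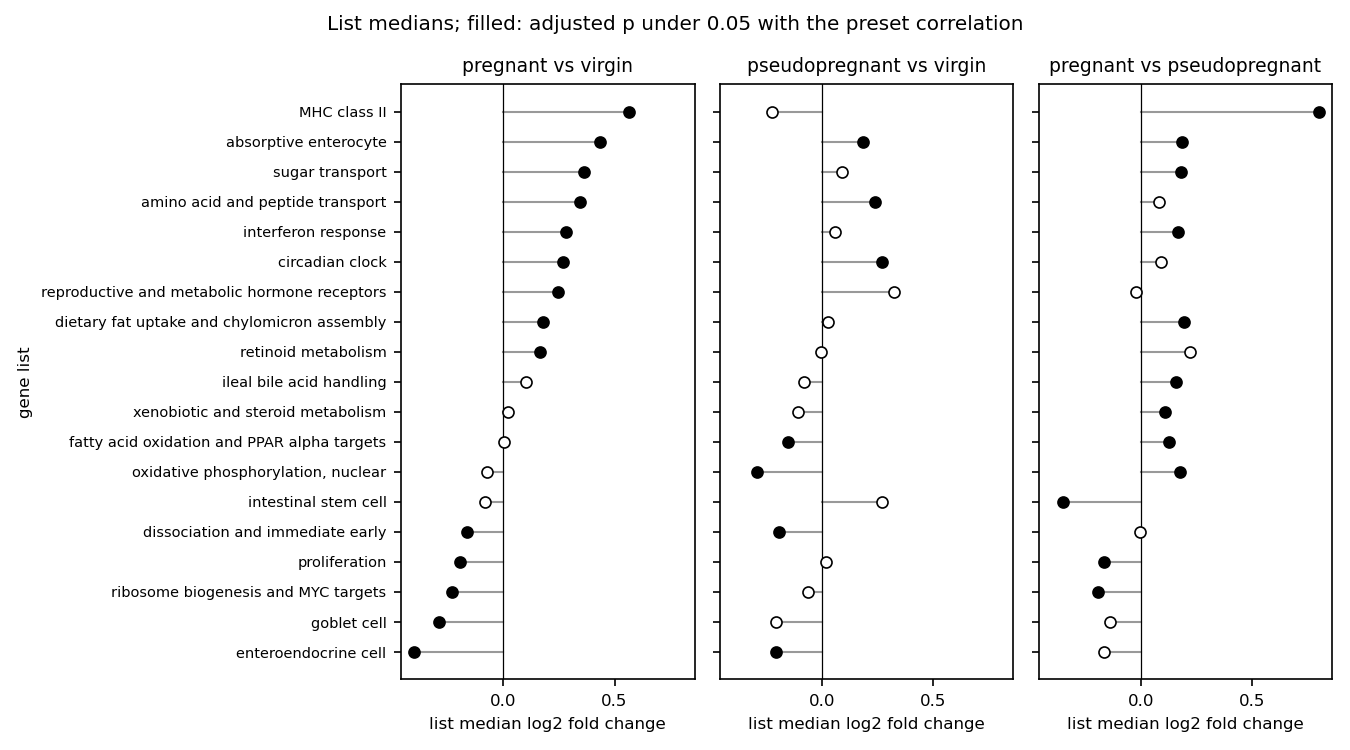
Median log2 fold change of the 19 gene lists that passed the list test in at least 1 of the 3 comparisons, with filled points where the adjusted p was under 0.05 with the preset correlation. Absorptive enterocyte genes stood at 0.44 and enteroendocrine genes at -0.40 in pregnant against virgin libraries, and 0 of the lists passed with an estimated correlation.

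The comparison of pseudopregnant with virgin libraries asked which transcripts differ between these 2 groups. Gm42427 was again among the genes of smallest p, at 38.5 ± 16.1 against 16.2 ± 3.76 CPM (log2 fold change 1.25, SE 0.27), and Bco1 was at 1.22 (SE 0.35). Cyp1a1, a xenobiotic-metabolising enzyme, stood at 1.51 ± 0.653 against 0.528 ± 0.159 CPM (1.52, SE 0.36), with all 6 pseudopregnant libraries above the virgin median, and Ppara, the nuclear receptor of fatty acid oxidation, at 19.2 ± 9.24 against 11.2 ± 1.502 CPM (0.79, SE 0.25). Slc5a4a was at 81.0 ± 42.0 against 65.1 ± 33.4 CPM (0.32, SE 0.36, and 0.060 to 0.63 when 1 library was left out), Prlr at 168 ± 17.7 against 135 ± 20.4 CPM (0.31, SE 0.12), and Mki67 at 91.3 ± 46.2 against 58.0 ± 13.5 CPM (0.65, SE 0.31), while Esr1 was at -0.07 (SE 0.45). None of these passed over all genes with edgeR (smallest adjusted p = 0.52).

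With edgeR 0 of 14675 genes passed, and 1375 (9.37%) had an unadjusted p under 0.05, 1080 of them higher and 295 lower in pseudopregnant libraries. Of 100 splits of these 12 libraries, the real one among them, 16 gave at least as many, as told below. Limma-voom (1107 at an unadjusted p under 0.05) and DESeq2 (1720) also called 0. The groups did not overlap in 10 genes (0.07%, chance 0.216%). Others of the 10 genes of smallest p were Serpina1f (0.79, SE 0.19), Tcf23 (-0.93, SE 0.22), Akap13 (0.92, SE 0.22), Bin1 (-0.86, SE 0.21) and Acnat2 (0.89, SE 0.22). To these came B3galt5, a galactosyltransferase (4.46, SE 1.10), the innate sensor kinase Alpk1 (1.63, SE 0.39) and A2ml1 (1.66, SE 0.41). The last 3 were each highest in pseudopregnant replicate 4, without which they were at 2.28, 1.09 and 1.13. Some of these genes had low counts: Acnat2 was at 0.673 to 1.88 CPM in the pseudopregnant libraries. Outside pseudopregnant replicate 4, A2ml1 was at most at 0.759 CPM and B3galt5 had a median of 0.825 CPM. The fold change of Gm42427 was 0.80 with the length slope and 0.82 with 1 surrogate variable in the model. The count of 1375 fell to 540 without pseudopregnant replicate 5, 635 without pseudopregnant replicate 4, 704 without virgin replicate 2, 738 without pseudopregnant replicate 2 and 792 without virgin replicate 1. It was 3390 without pseudopregnant replicate 1, 2585 without virgin replicate 3 and 2286 without pseudopregnant replicate 6.

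Nuclear genes of oxidative phosphorylation were lower in pseudopregnant libraries, with 36 of 39 negative (median -0.29, adjusted p = 2.84e-06, and adjusted p = 0.933 with an estimated correlation, as for each list of this comparison named here). Among them were Ndufs8 (-0.39, SE 0.21) and Uqcrfs1 (-0.29, SE 0.19, and -0.19 without pseudopregnant replicate 5). Their score fell with the length slope of a library (r = -0.95 over the 18 libraries), and with that slope as a covariate the median was 0.031 and the call ended. Fatty acid oxidation and PPAR alpha targets were negative in 20 of 24 (median -0.15, adjusted p = 0.00218). Adjusted over the list alone 1 of 24 passed, the acyl-CoA thioesterase Acot1 (-1.22, SE 0.32, adjusted p = 0.024, not passed without virgin replicate 4 or pseudopregnant replicate 4 or 5), a paralog of Acot2 (-0.62, SE 0.21) with which it may share reads. Ppara, the receptor itself, was at 0.79 as given above. The enteroendocrine list was negative in 19 of 22 (median -0.21, adjusted p = 0.0195), with Reg4 at -0.98 (SE 0.37), and dissociation genes in 17 of 18 (median -0.19, adjusted p = 0.00476), with Ier2 at -0.50 (SE 0.20, and -0.325 without virgin replicate 2). Higher were the lists of the circadian clock (16 of 17, median 0.27, adjusted p = 0.00476, Per3 at 0.89, SE 0.32, and 0 of 17 adjusted over the list alone) and amino acid and peptide transport (18 of 20, median 0.24, adjusted p = 0.00476). Absorptive enterocyte genes were higher too (17 of 21, median 0.19, adjusted p = 0.0187, Mgam at 0.64, SE 0.27). In the transporter list 1 of 20 passed adjusted over the list alone, the broad amino acid transporter Slc6a14 (adjusted p = 0.021), at 1.32 ± 2.10 against 0.155 ± 0.0912 CPM (3.08, SE 0.80, and 1.58 without pseudopregnant replicate 4). It did not pass without that library or virgin replicate 1, 2, 4 or 5.

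In all 7 of 35 lists passed, 3 higher and 4 lower, and for each of them the adjusted p = 0.933 with an estimated correlation. Fry called 0 lists (smallest adjusted p = 0.619), and over all alternatives the adjusted p of the 7 lists ran from 1.96e-08 (dissociation and immediate early) to 0.933. The absorptive enterocyte call ended without virgin replicate 2 (median 0.11), 5 (0.17) or 6 (0.15) and without pseudopregnant replicate 1 (0.17) or 3 (0.16), and with the length slope (0.080) as a covariate. The enteroendocrine call ended without virgin replicate 4 (-0.11) and pseudopregnant replicates 2 (-0.17) and 3 (-0.16), and with the length slope (-0.088). The dissociation call ended without virgin replicate 4 (-0.15) and pseudopregnant replicate 6 (-0.15), and that of amino acid and peptide transport with the length slope (0.048). Medians moved by over 1.5 times without virgin replicate 2 (oxidative phosphorylation -0.19, amino acid transport 0.15), virgin replicate 3 (enterocyte 0.38, amino acid transport 0.40), pseudopregnant replicate 5 (oxidative phosphorylation -0.19), pseudopregnant replicate 3 (clock 0.18) and pseudopregnant replicate 1 (enteroendocrine -0.44). With 2 surrogate variables the calls of oxidative phosphorylation (0.026), amino acid and peptide transport (0.041) and enteroendocrine genes (-0.096) ended. The number of lists was 15 without virgin replicate 3.

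The direct comparison of pregnant with pseudopregnant libraries tested whether the 2 states differ from each other. MHC class II genes were higher in pregnant libraries in 8 of 8 (median 0.80, adjusted p = 7.09e-06, and adjusted p = 0.788 with an estimated correlation). These 8 genes vary together (estimated correlation 0.92), and pseudopregnant replicate 5 had a list score of -3.05 (-0.28 to 0.57 in the other 5). H2-Aa stood at 448 ± 253 against 226 ± 131 CPM (log2 fold change 0.99, SE 0.68) and H2-Ab1 at 636 ± 307 against 358 ± 203 CPM (0.83, SE 0.56). Nuclear genes of oxidative phosphorylation were positive in 37 of 39 (median 0.18, adjusted p = 7.09e-06, and adjusted p = 0.788 with an estimated correlation), with Sdhb at 0.30 (SE 0.20, and 0.18 without pregnant replicate 1). Intestinal stem cell genes were lower in pregnant libraries in 17 of 18 (median -0.35, adjusted p = 0.00032, and adjusted p = 0.788 with an estimated correlation). Prom1 stood at 55.1 ± 9.47 against 76.9 ± 24.3 CPM (-0.48, SE 0.19), with Aqp4 at -0.83 (SE 0.34, and -0.52 without pseudopregnant replicate 4), Olfm4 at -0.49 (SE 0.45) and Lgr5 at -0.38 (SE 0.35), the last 2 at -0.30 and -0.10 without pseudopregnant replicate 5. Lgr5 was at -0.24 without pregnant replicate 3 and -0.59 without pregnant replicate 5. Slc5a4a stood at 148 ± 67.8 against 81.0 ± 42.0 CPM (0.87, SE 0.36, and 0.49 with 2 surrogate variables in the model) and Esr1 at 0.661 ± 0.292 against 0.315 ± 0.221 CPM (1.06, SE 0.41), each with all 6 pregnant libraries above the pseudopregnant median. Prlr differed by -0.04 (SE 0.12).

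With edgeR 0 of 14675 genes passed (smallest adjusted p = 0.92). An unadjusted p under 0.05 was held by 345 (2.35%, 112 higher, 233 lower in pregnant libraries). Of 100 splits of the 12 pregnant and pseudopregnant libraries, the real one among them, 52 gave at least as many. The median of the other splits was 362. Limma-voom (247 at an unadjusted p under 0.05) and DESeq2 (554) also called 0, and the groups did not overlap in 4 genes (0.03%, chance 0.216%). Among the 10 genes of smallest p were Fer1l4 (1.41, SE 0.37), the endocrine transcription factor Rfx6 (-1.15, SE 0.30), Mrgpre (-0.92, SE 0.26), Reg3d (-0.92, SE 0.27) and Lmx1a (-1.06, SE 0.31), the unannotated Gm42528 (-0.59, SE 0.18) and the tachykinin precursor Tac2 (1.496, SE 0.45). The others were Lrg1 (-3.90, SE 1.09), B3galt5 (-3.69, SE 1.05) and the fucosyltransferase Fut2 (-3.22, SE 0.95). These last 3 were each highest in pseudopregnant replicate 4, without which they were at -0.66, -1.52 and -0.17. Both group means of Fer1l4, Rfx6, Mrgpre, Reg3d, Lmx1a and Tac2 were under 2 CPM. The count of 345 fell to 120 without pseudopregnant replicate 4, 174 without pseudopregnant replicate 5, 204 without pregnant replicate 3 and 212 without pregnant replicate 4. It was 1568 without pseudopregnant replicate 1, 1004 without pregnant replicate 6, 770 without pseudopregnant replicate 3 and 574 without pseudopregnant replicate 6.

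**Figure D3:**
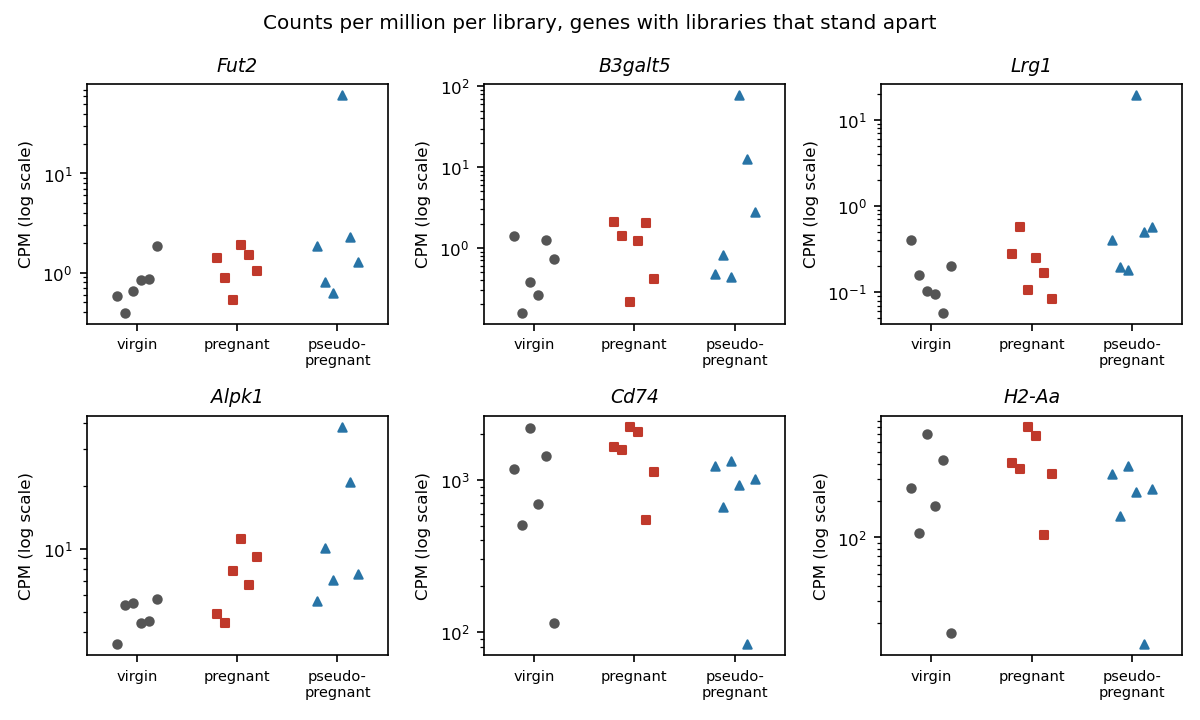
CPM (log axes) of 6 genes in each of the 18 libraries, by group. Pseudopregnant replicate 4 held 61.3 CPM of Fut2, 77.2 of B3galt5 and 19.3 of Lrg1, while pseudopregnant replicate 5 held 82.9 CPM of Cd74 and 13.4 of H2-Aa.

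Of 35 lists, 12 passed, 9 higher and 3 lower in pregnant libraries, each with an adjusted p = 0.788 with an estimated correlation, or 0.794 for proliferation. Besides the 3 above, ribosome biogenesis and MYC targets (27 of 30 negative, median -0.19, adjusted p = 0.000448, Utp20 at -0.59, SE 0.29) were lower. So was proliferation (28 of 34 negative, median -0.16, adjusted p = 0.00745, Mki67 at 57.1 ± 21.0 against 91.3 ± 46.2 CPM, -0.68, SE 0.31). Fatty acid oxidation and PPAR alpha targets (22 of 24 positive, median 0.13, adjusted p = 0.00101), with Cpt2 at 0.27 (SE 0.11) and Ppara at -0.63 (SE 0.25), were higher. So were dietary fat uptake (20 of 24, median 0.19, adjusted p = 0.00225, Plin2 at 0.32, SE 0.16, and 0.198 without pseudopregnant replicate 4) and interferon response (25 of 31, median 0.17, adjusted p = 0.00225). In the last, Gbp7 was at 1.05 (SE 0.46, and 0.615 without pregnant replicate 3), whereas the antiviral genes Mx1 and Oas2 were at -0.999 (SE 0.36) and -0.92 (SE 0.46), or -0.52 and -0.34 without pseudopregnant replicate 4. Sugar transport (15 of 18, median 0.18, adjusted p = 0.0109) and xenobiotic and steroid metabolism (25 of 37, median 0.11, adjusted p = 0.0109) were higher too, as were absorptive enterocyte (19 of 21, median 0.19, adjusted p = 0.0142) and ileal bile acid handling (10 of 12, median 0.16, adjusted p = 0.0328, Fgf15 at 0.54, SE 0.50, and 0.196 without pregnant replicate 3 or 0.33 without pseudopregnant replicate 6). Adjusted over the list alone, 0 members of these 12 lists passed. Fry called 0 (smallest adjusted p = 0.809), and over all alternatives the adjusted p of the 12 lists ran from 1.1e-08 (oxidative phosphorylation, nuclear) to 0.887 (proliferation).

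The number of lists fell from 12 to 3 without pregnant replicate 3 and to 7 without pregnant replicate 4 or pseudopregnant replicate 6, and was 20 without pregnant replicate 1. These sets were tested with the preset correlation, with which other splits of the 12 libraries called a median of 13 lists. A pass in every set is therefore weak evidence. MHC class II (medians 0.57 to 0.99) and the list oxidative phosphorylation, nuclear (0.065 without pregnant replicate 1, 0.082 without pseudopregnant replicate 5, 0.33 without pseudopregnant replicate 1) passed in all 12 sets that left out 1 library. Without pregnant replicate 3 the other calls ended, with medians of -0.25 for intestinal stem cell, -0.053 for proliferation, -0.099 for ribosome biogenesis, 0.066 for absorptive enterocyte and 0.13 for sugar transport. There the medians were 0.10 for dietary fat uptake, 0.083 for fatty acid oxidation, 0.10 for ileal bile acid handling, 0.040 for interferon response and 0.062 for xenobiotic metabolism. Without pregnant replicate 4 those of proliferation (-0.12), absorptive enterocyte (0.097), sugar transport (0.15), bile acid handling (0.084) and xenobiotic metabolism (0.091) ended, and without pregnant replicate 6 those of absorptive enterocyte (0.17), sugar transport (0.086), bile acid handling (0.24) and xenobiotic metabolism (0.091). Without pseudopregnant replicate 6 those of proliferation (-0.046), absorptive enterocyte (0.12), bile acid handling (0.076), interferon response (0.092) and ribosome biogenesis (-0.12) ended. Without pseudopregnant replicate 4 those of proliferation (-0.099), sugar transport (0.11), fatty acid oxidation (0.065), bile acid handling (0.11) and xenobiotic metabolism (0.034) ended, and without pseudopregnant replicate 5 those of interferon response (0.066) and xenobiotic metabolism (0.045). Without pregnant replicate 5 the call of bile acid handling (0.12) ended, and without pseudopregnant replicate 1 those of absorptive enterocyte (0.20) and sugar transport (0.17). Medians also moved by over 1.5 times without pregnant replicate 2 (bile acid 0.25), pregnant replicate 4 (interferon 0.11), pregnant replicate 5 (proliferation -0.26, ribosome biogenesis -0.29, sugar 0.29, interferon 0.28), pseudopregnant replicate 1 (bile acid 0.45, interferon 0.42). The same held for pseudopregnant replicate 2 (bile acid 0.079), pseudopregnant replicate 3 (proliferation -0.27, sugar 0.32, xenobiotic 0.16), pseudopregnant replicate 5 (stem cell -0.15, bile acid 0.10) and pseudopregnant replicate 6 (xenobiotic 0.23). With 2 surrogate variables 6 lists passed, and of the 12 only MHC class II (0.37) did so in the same direction: oxidative phosphorylation stood at 0.022 and the stem cell list at 0.10, and the proliferation list passed in the opposite direction (0.081). With the villus-minus-crypt score as a covariate 4 lists passed, and the calls of stem cell (-0.19), sugar transport (0.034), fat uptake (0.097), bile acid handling (0.12), interferon response (0.028), xenobiotic metabolism (0.008) and ribosome biogenesis (-0.066) ended.

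**Figure D4:**
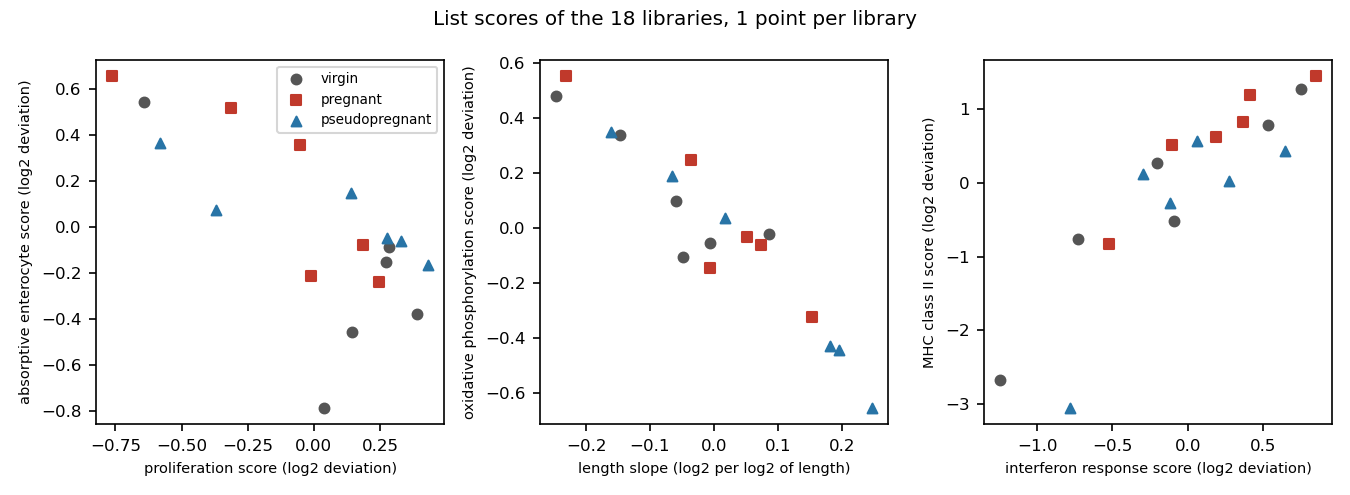
Scores of gene lists in the 18 libraries (mean log2 deviation from the mean of all libraries, 1 point per library): proliferation against absorptive enterocyte, nuclear oxidative phosphorylation against the length slope, and interferon response against MHC class II. The pairs had r = -0.72, -0.95 and 0.88, and the groups overlapped on every axis.

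Fold changes of the pregnant and of the pseudopregnant libraries, each against the same 6 virgin libraries, correlated across the 14675 genes with r = 0.643 (Spearman's rho 0.659, same sign in 75.1%). Genes are not independent replicates, and comparisons that share controls correlate without any effect. With all 18 libraries simulated as unchanged and genes varying independently, r was 0.497 (SD 0.012, 20 simulations). The real genes vary together, so that SD is too narrow to judge whether 0.643 exceeds what shared controls give. The covariance was 0.060 against 0.035 in the simulations, a difference of 0.025 under the same limit. With the virgin libraries split into 2 sets of 3, 1 for each comparison, r had a median of 0.20 (0.008 to 0.466 over 20 splits) and the covariance a median of 0.025 (0.001 to 0.048). The correlation was 0.420 to 0.745 when 1 library was left out.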

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

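The test of clock phase, the test of pseudopregnancy itself and the splits of the genes past the threshold were chosen only after the result was seen. Of 513 groups of 6 values, 39 (7.6%) held a library far from the other 5, by a gap over the range above Dixon's 95% critical value. Chance gives about 1 in 20.

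Pseudopregnant replicate 4 stood apart in genes of epithelial defence and beyond: Fut2 at 61.3 CPM (other pseudopregnant libraries 0.617 to 2.30), Lrg1 at 19.3 (0.182 to 0.572), A2ml1 at 2.52 (0.598 to 0.759) and Oas2 at 5.13 (0.875 to 1.71). Low were Bco1 at 9.64 (29.3 to 50.9), Dhrs3 at 28.8 (43.9 to 53.6) and Plin2 at 40.6 (70.4 to 88.1). Its antimicrobial score was 1.085, and the next highest were 0.368 and 0.353 (pregnant and pseudopregnant replicates 1). Saa1 was at 243 CPM (at most 52.7 in the 17 others), Reg3g at 11100 (4890), Duox2 at 657 (267) and B3galt5 at 77.2 (12.7). RNA from immune or stromal cells was tested: 0 of 4 lists of such cells had a mean log2 deviation above the other 17 libraries, but these lists held only 4, 4, 9 and 3 tested genes. The summed CPM of the T and intraepithelial lymphocyte list, 7.16, was above that of the others (at most 5.31), so such RNA stays open. Pseudopregnancy itself might raise these genes, but 0 of the other 5 pseudopregnant libraries had a score above the highest virgin or pregnant library. The highest of the 17 others was pseudopregnant for 11 of 22 genes of the list (6.5 expected), so a part of pseudopregnancy stays open, and a response of that 1 mouse or sample was not tested.

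Pseudopregnant replicate 5 was low in MHC class II: Cd74 at 82.9 CPM (659 to 1330 in the other 5), H2-Aa at 13.4 (150 to 381), H2-Ab1 at 37.3 (262 to 594), and H2-DMa at 8.83 (33.1 to 70.6). So were H2-DMb2 at 0.393 (2.59 to 5.63), H2-Eb1 at 17.7 (140 to 355) and the list score at -3.05 (-0.28 to 0.57), with Iigp1 at 0.197 (0.774 to 1.56). A low MHC class II score was not particular to that library, since virgin replicate 6 had -2.68. In pregnant replicate 5, H2-DMb2 was at 1.75 CPM (4.73 to 7.49), Iigp1 at 0.169 (1.49 to 3.99), and Gcg high at 63.5 (27.2 to 34.2). Virgin replicate 3 was low in dividing-cell and ribosome biogenesis genes: Aurka at 12.6 CPM (21.8 to 24.8), Tk1 at 13.6 (25.2 to 34.5), Myc at 11.1 (24.4 to 33.5), Gar1 at 7.45 (up to 23.1), Nop58 at 33.8 (61.9 to 76.3) and Rrs1 at 8.42 (14.9 to 18.2). It had scores of -0.64 for proliferation (0.04 to 0.39) and -0.57 for ribosome biogenesis and MYC targets (0.15 to 0.35), and was high in Clock at 53.0 (36.3 to 41.3). Both scores were also the lowest of their group in pregnant replicate 3 (-0.76 and -0.74) and pseudopregnant replicate 3 (-0.58 and -0.55). Virgin replicate 4 was high in mitochondrial transcripts at 8.667% (5.238 to 6.323), in the share of its 10 highest genes at 12.52% (8.803 to 10.178) and in Bcas1 at 48.1 CPM (19.2 to 26.1). Single values apart were Slc9a3 at 0.553 CPM in virgin replicate 2 (8.96 to 26.2), Axin2 at 30.9 (51.5 to 66.9) and Gm42427 at 24.5 (40.3 to 53.8) in pregnant replicate 1, and Akr1b8 at 4.06 in pregnant replicate 2 (1.32 to 1.88). Rfx6 was at 1.17 CPM in pregnant replicate 6 (0.392 to 0.563) and 0.472 in pseudopregnant replicate 3 (1.21 to 1.83). Acnat2 was at 0.673 (1.34 to 1.88) and Prlr at 134 (166 to 185) in pseudopregnant replicate 6, and the goblet cell score at 0.34 in pseudopregnant replicate 1 (-0.16 to 0.02).

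The clock list was higher in pregnant than virgin libraries (median 0.27). With the length slope as a covariate the median was 0.242 (0.191 to 0.31 when 1 library was left out), so length is unlikely to be the whole cause. With the villus-minus-crypt score it was 0.169 (0.128 to 0.237), and the list still passed with the preset correlation. With an estimated correlation it did not pass even without that covariate (adjusted p = 0.195). The median fell but did not vanish, so a different share of villus and crypt cells stays open as a cause of part or all of it. A shifted phase was tested by setting 9 genes of the Dbp phase (mean log2 fold change 0.62) against 4 of the opposite phase (0.07): the difference was 0.55 (SE 0.24, n = 6, exact two-sided permutation p = 0.0455, adjusted p = 0.136 over the 3 comparisons). Dbp, Tef, Hlf, Per3, Nr1d1 and Nr1d2, already seen to be higher, were among these 9, so the test partly restates that result. The 4 opposite genes did not fall, and the difference did not pass adjustment, so a shifted phase stays open. A later or earlier hour of collection could give such a shift as well as pregnancy could, and the labels give no hour.

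Nuclear oxidative phosphorylation genes were lower in pseudopregnant than virgin libraries (median -0.293). With the length slope the median was 0.031 (-0.01 to 0.093 when 1 library was left out), so a trend with transcript length between libraries, as RNA quality or library preparation can give, could account for it. These genes are short and were themselves among the genes that set the slope, so a real fall might also be taken up by it. With the villus-minus-crypt score the median was -0.254 (-0.377 to -0.141) and the list still passed with the preset correlation. With an estimated correlation it did not pass even without that covariate (adjusted p = 0.933). Most of the median remained, but the range is wide, so a different share of villus and crypt cells stays open.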

How the results depend on the processing

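The alternatives of dispersion method, 2 surrogate variables and the 2 covariates, and the sets without 1 library for members past adjustment over their list alone, were chosen only after the result was seen. The 0 genes past the threshold in each comparison stayed 0 in all alternatives except that DESeq2 called 2 and the replicate block called 1 (Gm42427) in pregnant against virgin libraries. With the block, 979, 1988 and 618 genes had an unadjusted p under 0.05 (540, 1375 and 345 without it). Whether equal replicate numbers pair libraries was not settled: their correlations ran from -0.48 to 0.66, with 10 of 18 over 0.1 (replicates 1, 3 and 5 in all 3 pairs), and 5 of 18 libraries correlated best with their own number. Of the 660 alternatives of 33 list results in the 3 comparisons, 501 kept the call and direction, 144 were weaker and 15 changed sign. The median SE was 0.202, and replicates differed by at least 35.5 times the variance of sampling, so at this depth the spread between libraries and not the number of reads set that error for well expressed genes. Lists called with an estimated correlation were 0, 0 and 0, and with fry 0, 0 and 0. In pregnant against pseudopregnant libraries 6 lists passed with 2 surrogate variables, 19 with the length slope and 4 with the villus-minus-crypt score, and 3 to 20 when 1 library was left out. In pseudopregnant against virgin libraries 5 to 15 did. The correlation between the 2 comparisons with virgin libraries was 0.20 with split virgin libraries, which removes the shared controls and leaves 3 virgin libraries for each. The cause was not tested for the others.

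Values that changed sign follow, each with the value of the model used in the report in brackets. With 1 surrogate variable, pseudopregnant against virgin libraries gave Epcam 0.050 (-0.14), Fabp6 0.097 (-0.53), Olfm4 -0.048 (0.57), Pgr -0.30 (0.008), S100g 0.38 (-0.26), Slc2a2 -0.032 (0.25). Further values there were Slc9a3 -0.205 (1.39). In pregnant against virgin libraries this gave Fabp6 0.295 (-0.16), Lgr5 -0.066 (0.076), Olfm4 -0.105 (0.077), S100g 0.029 (-0.33). In pregnant against pseudopregnant libraries this gave Pgr 0.13 (-0.035). With 2 surrogate variables, pseudopregnant against virgin libraries gave Ace -0.015 (0.51), Epcam 0.034 (-0.14), Fabp6 0.066 (-0.53), nuclear oxidative phosphorylation list 0.026 (-0.29), Pgr -0.28 (0.008), S100g 0.46 (-0.26). Others in that set were Slc2a2 -0.12 (0.25), Slc2a5 -0.011 (0.10), Slc9a3 -0.22 (1.39). In pregnant against pseudopregnant libraries this gave Cenpf 0.024 (-0.59), dietary fat uptake and chylomicron assembly list -0.011 (0.19), Epcam -0.019 (0.19), Heatr1 0.015 (-0.52), interferon response list -0.085 (0.17), intestinal stem cell list 0.10 (-0.35). To these came Kif11 0.033 (-0.41), Lgr5 0.15 (-0.38), Olfm4 0.20 (-0.49), Pgr 0.40 (-0.035), proliferation list 0.081 (-0.16), ribosome biogenesis and MYC targets list 0.009 (-0.19). Further values there were Top2a 0.049 (-0.44), xenobiotic and steroid metabolism list -0.033 (0.11). In pregnant against virgin libraries this gave dietary fat uptake and chylomicron assembly list -0.002 (0.18), Fabp6 0.13 (-0.16), interferon response list -0.007 (0.28), Mki67 0.084 (-0.022), Pgr 0.12 (-0.027), proliferation list 0.049 (-0.19). Others in that set were S100g 0.19 (-0.33), Slc2a2 -0.061 (0.44). With DESeq2, pregnant against pseudopregnant libraries gave Pgr 0.004 (-0.035). In pseudopregnant against virgin libraries this gave Pgr -0.026 (0.008). In pregnant against virgin libraries this gave Ptprc 0.009 (-0.004). With DESeq2 size factors, pregnant against virgin libraries gave Ptprc 0.007 (-0.004). With the default dispersion method, pseudopregnant against virgin libraries gave Pgr -0.010 (0.008). In pregnant against virgin libraries this gave Ptprc 0.000 (-0.004). With the length slope as a covariate, pseudopregnant against virgin libraries gave Epcam 0.038 (-0.14), Fabp6 0.068 (-0.53), Ndufa8 0.003 (-0.37), Olfm4 -0.037 (0.57), nuclear oxidative phosphorylation list 0.031 (-0.29), Pgr -0.32 (0.008). To these came S100g 0.39 (-0.26), Slc2a2 -0.032 (0.25), Slc6a6 -0.006 (0.48), Slc9a3 -0.22 (1.39). In pregnant against virgin libraries this gave Fabp6 0.28 (-0.16), Lgr5 -0.073 (0.076), Olfm4 -0.14 (0.077), S100g 0.040 (-0.33). In pregnant against pseudopregnant libraries this gave Pgr 0.13 (-0.035). With limma-voom, pregnant against virgin libraries gave Apoa4 0.19 (-0.079), Pgr 0.205 (-0.027). In pregnant against pseudopregnant libraries this gave Pgr 0.29 (-0.035). In pseudopregnant against virgin libraries this gave Pgr -0.082 (0.008). With mitochondrial genes left out, pseudopregnant against virgin libraries gave Pgr -0.006 (0.008). With only the 12 libraries compared, pregnant against virgin libraries gave Ptprc 0.005 (-0.004). With the replicate number as a block, pregnant against virgin libraries gave Apoa4 0.16 (-0.079). In pseudopregnant against virgin libraries this gave Pgr -0.034 (0.008). With upper-quartile scaling, pseudopregnant against virgin libraries gave Pgr -0.029 (0.008). With the villus-minus-crypt score as a covariate, which contains the proliferation list itself, pregnant against virgin libraries gave dietary fat uptake and chylomicron assembly list -0.029 (0.18), Epcam -0.067 (0.050), Mki67 0.29 (-0.022), Pgr 0.23 (-0.027), proliferation list 0.099 (-0.19), ribosome biogenesis and MYC targets list 0.028 (-0.23). Further values there were Tk1 0.012 (-0.315). In pregnant against pseudopregnant libraries this gave Pgr 0.083 (-0.035), proliferation list 0.015 (-0.16), Slc2a2 -0.015 (0.20). In pseudopregnant against virgin libraries this gave Slc2a5 -0.049 (0.10), Slc5a1 -0.003 (0.12).

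When 1 library was left out, values ran across 0 as follows. For pregnant against virgin libraries these were Ptprc -0.23 to 0.16 (-0.004), Olfm4 -0.145 to 0.29 (0.077), Fabp6 -0.45 to 0.29 (-0.16), S100g -0.50 to 0.12 (-0.33), Lgr5 -0.14 to 0.22 (0.076). Also there, Apoa4 -0.27 to 0.35 (-0.079), Mki67 -0.22 to 0.095 (-0.022), Pgr -0.23 to 0.40 (-0.027), Epcam -0.011 to 0.13 (0.050), Slc2a2 -0.001 to 0.64 (0.44). For pseudopregnant against virgin libraries these were Pgr -0.48 to 0.43 (0.008), Slc2a5 -0.034 to 0.29 (0.10), S100g -0.48 to 0.17 (-0.26), Esr1 -0.48 to 0.16 (-0.065), Slc5a4b -0.38 to 0.096 (-0.21). Also there, Slc5a1 -0.006 to 0.245 (0.12). For pregnant against pseudopregnant libraries these were Pgr -0.24 to 0.45 (-0.035), Prlr -0.094 to 0.028 (-0.038), S100g -0.21 to 0.16 (-0.064), Slc2a2 -0.25 to 0.39 (0.20).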

Other observations

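The score relations below were chosen after the libraries had been seen. Some gene groups that passed no list test held single members past adjustment over the list alone in pseudopregnant against virgin libraries, among them genes named after their values were seen. Dmbt1, a mucosal defence protein, was at 1.65 (SE 0.48) in the lists of villus base antimicrobial (1 of 10) and antimicrobial and host defence genes (2 of 22), the latter with the acute phase gene Saa1 (3.41, SE 1.05), which was highest in pseudopregnant replicate 4. Without that library Dmbt1 was at 0.93 and Saa1 at 1.63 and these passes ended, as they did without virgin replicates 1 to 4 or pseudopregnant replicate 5, and in 1 of the 2 lists without virgin replicate 5 or 6. Cyp1a1 passed in xenobiotic and steroid metabolism (1 of 37), Bco1 in retinoid metabolism (1 of 11) and Id4 (-1.09, SE 0.29) in BMP and TGF beta targets (1 of 12). These passes also ended without single libraries: Cyp1a1 without virgin replicate 4 or 5 or pseudopregnant replicate 4, Id4 without virgin or pseudopregnant replicate 4, and Bco1 without virgin replicate 2, 5 or 6 or pseudopregnant replicate 1, 3 or 5. Paneth cell genes were lower in 16 of 17 in that comparison (median -0.43, adjusted p = 0.258) and hormone receptors higher in 10 of 14 (median 0.32, adjusted p = 0.0738). In pregnant against virgin libraries the lists of calcium, phosphate and vitamin D (median 0.13) and of iron and metal handling (median 0.18) each had an adjusted p = 0.0509. The ileal hormone Fgf15 stood at 83.5 ± 55.0 CPM in pregnant, 57.3 ± 33.6 in pseudopregnant and 43.4 ± 24.4 in virgin libraries (0.94 for pregnant against virgin, and 0.595 without pregnant replicate 3).

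In some lists that did not pass, the median and the mean fold change or the direction of the test differed in sign. For pregnant against virgin libraries the median and mean were 0.064 and 0.003 for villus base antimicrobial (test lower), 0.004 and -0.13 for fatty acid oxidation (lower), -0.008 and -0.070 for mineralocorticoid response (higher) and 0.022 and -0.006 for xenobiotic metabolism (higher). For pseudopregnant against virgin libraries they were 0.016 and -0.015 for proliferation (lower), -0.066 and 0.001 for villus tip (higher), 0.015 and -0.040 for cholesterol synthesis (lower), -0.003 and 0.40 for antimicrobial and host defence (higher). They were 0.014 and -0.064 for mineralocorticoid response (lower), -0.003 and 0.15 for retinoid metabolism (higher), -0.012 and 0.048 for glycolysis (lower) and -0.055 and 0.041 for unfolded protein response (lower). For pregnant against pseudopregnant libraries they were 0.026 and 0.006 for myeloid cell (lower), 0.084 and -0.083 for amino acid transport (higher), 0.016 and -0.005 for cholesterol synthesis (lower), -0.015 and 0.041 for calcium handling (higher), -0.023 and 0.043 for hormone receptors (higher) and 0.004 and -0.006 for mineralocorticoid response (higher).

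Across the 18 libraries 6 relations between scores were tested with 100000 permutations, whose smallest possible p is 1e-05. Absorptive enterocyte and proliferation scores had r = -0.72 (permutation p = 0.00062, rho -0.63 with p = 0.0059, r = -0.78 without the 2 farthest libraries and -0.66, -0.87 and -0.86 within virgin, pregnant and pseudopregnant libraries, BH p = 0.00074). MHC class II and interferon response had r = 0.88 (permutation p = 1e-05, rho 0.87 with p = 1e-05, 0.85 without the 2 farthest, and 0.94, 0.95 and 0.79 within groups, BH p = 2e-05). MHC class II and absorptive enterocyte had r = 0.54 (permutation p = 0.021, rho 0.54 with p = 0.022, 0.68, and 0.59, 0.70 and 0.34 within groups, BH p = 0.021). Proliferation and ribosome biogenesis had r = 0.97 (permutation p = 1e-05, rho 0.91 with p = 1e-05, 0.94, and 0.96, 0.94 and 0.99, BH p = 2e-05). Length slope and nuclear oxidative phosphorylation had r = -0.95 (permutation p = 1e-05, rho -0.89 with p = 1e-05, -0.93, and -0.87, -0.93 and -0.99, BH p = 2e-05). The absorptive enterocyte score and Slc5a4a had r = 0.80 (permutation p = 9e-05, rho 0.67 with p = 0.0026, 0.71, and 0.98, 0.97 and 0.49, BH p = 0.00014).

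Whether the counts of the comparisons exceed those of other groupings was tested by 100 splits of the 12 libraries of each comparison into 2 sets of 6, the real one among them. A real count of 0 genes is reached by every split, so that count decides nothing. The highest and median are those of the other 99. For pregnant against virgin libraries, 100 splits called at least the real 0 genes (highest 1791, median 0), 31 gave at least the real 540 genes at an unadjusted p under 0.05 (highest 4859, median 290) and 57 at least the real 14 lists (highest 22, median 14). For pseudopregnant against virgin libraries these were 100 (highest 4411, median 0), 16 for the real 1375 genes (highest 6376, median 336) and 95 for the real 7 lists (highest 22, median 13). For pregnant against pseudopregnant libraries they were 100 (highest 1, median 0), 52 for the real 345 genes (highest 4280, median 362) and 59 for the real 12 lists (highest 21, median 13). The real counts of genes at an unadjusted p under 0.05 and of lists did not stand out from the other splits. The splits took no account of replicate number, on which the real groups are balanced and most other splits are not. If equal numbers pair libraries, which was not settled, other splits could gain counts from that. Chance may therefore account for the real counts, but these splits cannot decide it. Splits that called 1791 and 4411 genes, where the real groups called 0, point to a structure of the samples other than mating status.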
